A study of Mus musculus with 12 samples.

How the data were processed

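RNA of 12 mouse heart libraries was sequenced in 6 groups of 2, by arm (AngII or sham) and gastrodin dose (0, 5 or 50 mg/kg/day). Total RNA was extracted with the RNeasy Plus Mini kit, libraries were made from 1 µg with the TruSeq RNA kit, and they were sequenced as paired ends of up to 250 bases on a NovaSeq instrument. Per the submitters' processing notes, HISAT2 2.2.1 and StringTie 2.1.3 were used on the mouse genome GRCm38.p6; the role of each, the program that counted reads, the annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. The deposited matrix holds raw counts for 27504 genes without normalisation by the authors, of which 27453 had a symbol and 51 had none. The deposited TPM values list 14271 genes and, per the file headers, are TPM; within a gene and library each equals the count times a constant, with a largest relative departure of 8.9e-10. Sex is not given in the sources used here.

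Gene positions, biotypes and overlaps were taken from GENCODE M21 on GRCm38. The counts were sorted into 37 mitochondrial genes, 7 genes with at least 50% of their 31-base words shared with the mitochondrial genome, 40 ribosomal RNA loci and all others. Since the strand is not known, genes that overlap on either strand and genes with near-identical copies are uncertain, and 2165 genes share exon bases with another on the same strand.

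Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (16723 genes), scaled by TMM, and fitted with 1 mean per group over all 12 libraries, which left 6 residual degrees of freedom (prior 6.93, common dispersion 0.227, a biological coefficient of variation of 0.476). Contrasts were tested with edgeR's quasi-likelihood F-test, 2-sided, and adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were AngII against sham in vehicle and averaged over 3 doses, each dose against vehicle within each arm, both doses together against vehicle and 50 against 5 mg in AngII, and the interaction at each dose. Standard errors were taken as the log2 fold change divided by the root of F. CPM are counts scaled by the TMM-adjusted library size. A fold against a group with no count is a lower bound, with a floor of 3 counts over the group's libraries together. The 95% intervals of shares are Wilson intervals.

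Gene lists for pathways and cell types were written before the data were examined, as were the groups, the tests, the alternatives not stated otherwise and the rule for the genes named. The lists of hepatocyte genes and of nuclear-retained RNAs used further below were not among them. Of 37 lists, 35 had at least 5 tested members; lung (4) and thymus (3) were not tested. They were tested with camera in limma 3.58.1 on log2 CPM with an inter-gene correlation of 0.01, adjusted over the 35 lists of a contrast, again with an estimated correlation, and with fry. The rule names, for AngII against sham and for each dose in AngII, the 8 largest rises and falls among called genes with a mean log2 CPM of at least 1 and no overlap between libraries. It also names 10 fixed genes (Nppa, Nppb, Myh7, Myh6, Acta1, Col1a1, Col3a1, Postn, Igf2 and Igf2r), and for each called list the 4 members with the smallest p. Other contrasts take 4 rises and 4 falls, contrasts with fewer than 5 calls take all called genes and the 5 smallest p, and predicted genes are skipped among rises and falls. The rule's full set is larger than the set printed: for lists the text names only some of the 4 members, picked after their values were seen, and for the averaged gastrodin, dose and interaction contrasts only some of the lists. Genes outside the rule are marked as picked after their values were seen. Values of 2 genes that the rule names are not reported here.

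Alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, limma-voom, no filter, at least 1 CPM in 6 libraries, only the compared groups, mitochondrial and haemoglobin genes left out, an added 1.5-fold limit, limma-trend on log2(TPM + 1), a prior count of 5 and each library left out in turn. With a library left out, filterByExpr was run again by group, and a group with a lone library loosens it. Chosen after seeing the data were overlapping genes summed (1390 genes joined, 26687 units in all), the nuclear share of counts as a covariate, libraries 4 and 12 left out together, and removal of each library's trend on GC content. The covariance of AngII and gastrodin effects was set against 20 simulations with the AngII vehicle libraries shared; those without each library in turn and with at least 1 CPM in 6 libraries were added after seeing the data. Counts were also simulated, independently for each gene, with genes changed by 2, 4 and 8-fold. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery below that level was not tested. The pipeline was run on these simulated data. It recovered 0, 52.2 and 90.9% for AngII vehicle against sham vehicle (5 false of 100 calls), 38.8, 94.0 and 100% for the average (6 of 161), and 0, 52.2 and 86.4% for 50 mg in AngII (7 of 99).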

Results

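RNA from hearts of C57BL/6 mice at postnatal day 45 was sequenced as 12 libraries in 6 groups, with 2 libraries per group. Mice of the AngII arm carried a model of cardiac hypertrophy made with angiotensin II, a peptide hormone that constricts vessels and drives growth of heart muscle. Mice of the sham arm had the control operation. Within each arm the mice received vehicle or gastrodin, a phenolic glucoside of the orchid Gastrodia elata, by the gastric route at 5 or 50 mg/kg/day for 7 days. Libraries are named here by arm, dose and their number from 1 to 12. The labels do not say whether each library came from a separate animal, so the p-values measure only the spread between these samples.

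Total counts were 74.4 and 78.6 M in AngII vehicle (numbers 1 and 2), 74.9 and 72.1 M in AngII 5 mg (numbers 3 and 4), and 74.4 and 73.6 M in AngII 50 mg (numbers 5 and 6). They were 73.3 and 78.0 M in sham vehicle (numbers 7 and 8), 70.8 and 63.5 M in sham 5 mg (numbers 9 and 10), and 73.8 and 72.3 M in sham 50 mg (numbers 11 and 12). Mitochondrial transcripts took 63.1 to 74.5% of the counts, and 7 nuclear pseudogenes with mitochondrial sequence took a further 15.9 to 19.5%. Ribosomal RNA loci held 10.8% in sham 50 mg number 12 (Wilson 95% interval 10.8186 to 10.8329%), 0.959% in sham 5 mg number 10 (0.956 to 0.961%), and at most 0.184% elsewhere; intervals and floors cover counting error only. All other genes, on which the comparisons rest, held 6.34 to 20.3% of the counts, or 4.49 to 15.2 M. Their share was 13.3 ± 5.28% in the AngII arm and 8.14 ± 1.51% in the sham arm (SD, n = 6 each; 2-sided exact permutation p = 0.0455 over 924 splits). On the first principal component, which held 30.0% of the variance, AngII 5 mg number 4 lay at 12.2, the other AngII libraries at -91.3 to -40.3 and the sham libraries at 37.3 to 78.6.

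**Figure D1:**
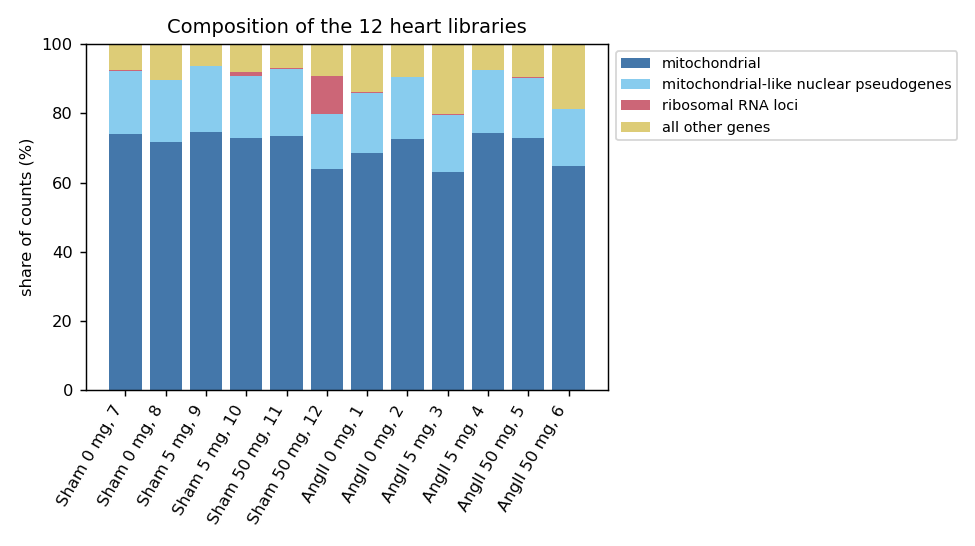
Share of all counts (%) held by 4 classes of genes in each of the 12 heart libraries. Mitochondrial genes took 63.1 to 74.5%, and ribosomal RNA loci stood out in sham 50 mg number 12 at 10.8%.

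AngII vehicle against sham vehicle hearts asks what angiotensin II did without gastrodin. The genes that rose included Mir208b, a microRNA in an intron of the myosin gene Myh7, and Rnf207, an E3 ubiquitin ligase tied to cardiac repolarisation. Mir208b stood at 3.69 ± 1.14 against 0.146 ± 0.0119 CPM (SD, n = 2 each; log2 fold change 4.66 ± 0.71 SE, edgeR adjusted p = 0.0468), and its count does not tell the microRNA from unspliced RNA of Myh7. Rnf207 stood at 68.0 ± 26.0 against 6.58 ± 2.17 CPM (log2 fold change 3.37 ± 0.53, edgeR adjusted p = 0.0468), on chromosome 4 at 152307019 to 152318993 of GRCm38, where it overlaps Icmt on the opposite strand. The receptor gene Notch2, the splicing factor gene Luc7l and Errfi1, an inhibitor of EGF receptor signalling, rose by log2 fold changes of 3.35 ± 0.51, 2.41 ± 0.32 and 2.21 ± 0.32; Notch2 is uncertain because it shares exon bases with Gm42820. Mlxip, which encodes the glucose-responsive transcription factor MondoA, fell by a log2 fold change of -2.36 ± 0.37 (0.918 ± 0.0977 against 4.69 ± 0.964 CPM, edgeR adjusted p = 0.0468), a call that held in 4 of 12 fits with 1 library left out each.

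Of 16723 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 8 higher and 2 lower. Scgb3a1, a secretoglobin gene, was at least 100.5-fold higher, since neither sham vehicle library held a count. Lung markers (4 genes, too few to be tested) also lay higher in AngII vehicle. Their median deviation from the mean of the 12 libraries was 2.13 and 1.89 (log2) there, and 0.13 and -2.17 in sham vehicle. Hsd3b7, an enzyme of bile acid synthesis, rose by 4.47 ± 0.62 and the predicted gene Gm28035 by 5.77 ± 0.91 on the log2 scale, but with overlapping genes on the same strand summed the values were 1.17 and 0.52 and neither passed. Scgb3a1, Gm28035 and Gm49394, which overlaps Igf2, were picked after their values were seen.

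Of the markers of cardiac growth, Nppa, Nppb and Acta1 lay lower in AngII vehicle and Myh7 higher, without passing over all genes. Nppa, the atrial natriuretic peptide gene that heart muscle makes under load, stood at 197 ± 9.80 against 512 ± 266 CPM (SD, n = 2 each; log2 fold change -1.38 ± 0.42, edgeR adjusted p = 0.172). The log2 fold changes were -0.80 ± 0.33 for its relative Nppb, -1.70 ± 0.43 for skeletal actin Acta1, 0.66 ± 0.47 for adult myosin Myh6 and 0.43 ± 0.41 for fetal myosin Myh7. They were -0.39 ± 0.45 for Col1a1, -0.15 ± 0.40 for Col3a1, -1.05 ± 0.48 for the matrix gene Postn and 1.40 ± 0.41 for the receptor Igf2r, with adjusted p from 0.119 to 0.884 among these genes and Igf2. For Nppa, Nppb and Acta1 this direction is opposite to what a model of hypertrophy leads one to expect; the arms are named here as labelled. Of 18 measured genes of the fetal and hypertrophy programme 0 passed over all genes, and 5 fell when adjusted over the list alone. Among them, Csrp3, Xirp2 and Ankrd1, which encode stress-responsive muscle proteins, were at -1.50 ± 0.34, -1.62 ± 0.27 and -1.78 ± 0.43. The list as a whole was lower (camera adjusted p = 0.000748; adjusted p = 0.545 with an estimated correlation).

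Vessel genes lay higher. Of 12 smooth muscle and pericyte markers 7 rose when adjusted over the list alone, among them Acta2 (104 ± 63.6 against 18.0 ± 4.43 CPM; log2 fold change 2.52 ± 0.52), Tagln (2.94 ± 0.71) and Notch3 (2.05 ± 0.49), and 0 passed over all genes. Of 12 endothelial markers 4 rose when adjusted over the list alone, among them Vwf (1.69 ± 0.41) and Esam (1.67 ± 0.45), and of 24 immediate-early genes 1 did so (Egr2, at least 18.3-fold higher with no count in sham vehicle), with Dusp1 at 1.49 ± 0.47 and Fosb at 4.45 ± 1.33. Of 8 mesothelial and epicardial markers 0 passed either way, with Msln at 3.85 ± 1.52 and Wt1 at 1.20 ± 0.71. Camera adjusted p for these 4 lists ran from 5.35e-05 to 0.0237 (adjusted p = 0.545 to 0.560 with an estimated correlation). Of 42 ribosomal protein genes 12 fell when adjusted over the list alone and 0 over all genes, with Rps13 at -1.28 ± 0.34 and Rplp0 at -1.18 ± 0.34; reads of such genes are uncertain because of their many pseudogenes. The lists for nuclear-encoded oxidative phosphorylation (41 genes; Cox5a -1.04 ± 0.30, Atp5g3 -0.66 ± 0.29), fatty acid oxidation (30; Fabp3 -0.88 ± 0.33, Decr1 -0.85 ± 0.34), antioxidant genes (25; Gpx1 -1.10 ± 0.44, Srxn1 -1.02 ± 0.34) and the cell cycle (30; Mcm6 -1.19 ± 0.43, Pcna -1.11 ± 0.54) were also lower, with 0 members passing over all genes or adjusted over the list alone. Camera adjusted p for these 5 lists ran from 3.55e-19 to 0.0153 (adjusted p = 0.560 with an estimated correlation for each).

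An unadjusted p under 0.05 was reached by 2752 genes, against 836 by chance; DESeq2 called 718 and limma-voom 5. The count of 10 was 0 without AngII vehicle number 1 or sham vehicle number 7 or 8, 25 without AngII vehicle number 2, 34 without AngII 50 mg number 5, and 479 and 535 without AngII 5 mg number 3 or 4. It was 6 with mitochondrial and haemoglobin genes left out, 86 with the nuclear share of counts as a covariate, and 2 (Scgb3a1 and Luc7l) with overlapping genes summed, where Mir208b, Rnf207, Notch2, Errfi1 and Mlxip had edgeR adjusted p of 0.0506 to 0.0517. With 1 library left out each, the calls of the genes named as called held in 4 (Mlxip), 7 (Rnf207), 8 (Mir208b) and 9 (the others) of 12 fits. None held without AngII vehicle number 1 or sham vehicle number 7 or 8. Of the list calls, 8 of 10 held in all 12. The antioxidant and mesothelial calls did not (camera adjusted p up to 0.161 and 0.0774).

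Averaging the 3 doses, AngII against sham hearts asks what angiotensin II changed whatever the dose. Nppa fell to 170.3 ± 48.6 against 485 ± 156 CPM (SD, n = 6 each; log2 fold change -1.56 ± 0.24 SE, edgeR adjusted p = 0.00197), and it lay lower in all 6 AngII libraries than in any sham library. Nppa lies on chromosome 4 at 148000722 to 148002079 of GRCm38 and overlaps Gm13054 on the opposite strand. Nppb (log2 fold change -1.08 ± 0.19), Acta1 (-1.32 ± 0.25), Ankrd1 (-1.68 ± 0.25) and Xirp2 (-1.14 ± 0.15) fell as well. Myh6, the adult myosin heavy chain, rose (3202 ± 1134 against 1294 ± 455 CPM; log2 fold change 1.34 ± 0.28), as did Myh7 (1.12 ± 0.24) and Igf2r (1.02 ± 0.24, edgeR adjusted p = 0.0110), while Igf2 did not pass (-0.47 ± 0.42, edgeR adjusted p = 0.432). The matrix genes Col1a1 (-0.89 ± 0.26), Col3a1 (-1.04 ± 0.23; uncertain, since Gm47302 shares its exons) and Postn (-1.93 ± 0.28) fell.

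**Figure D2:**
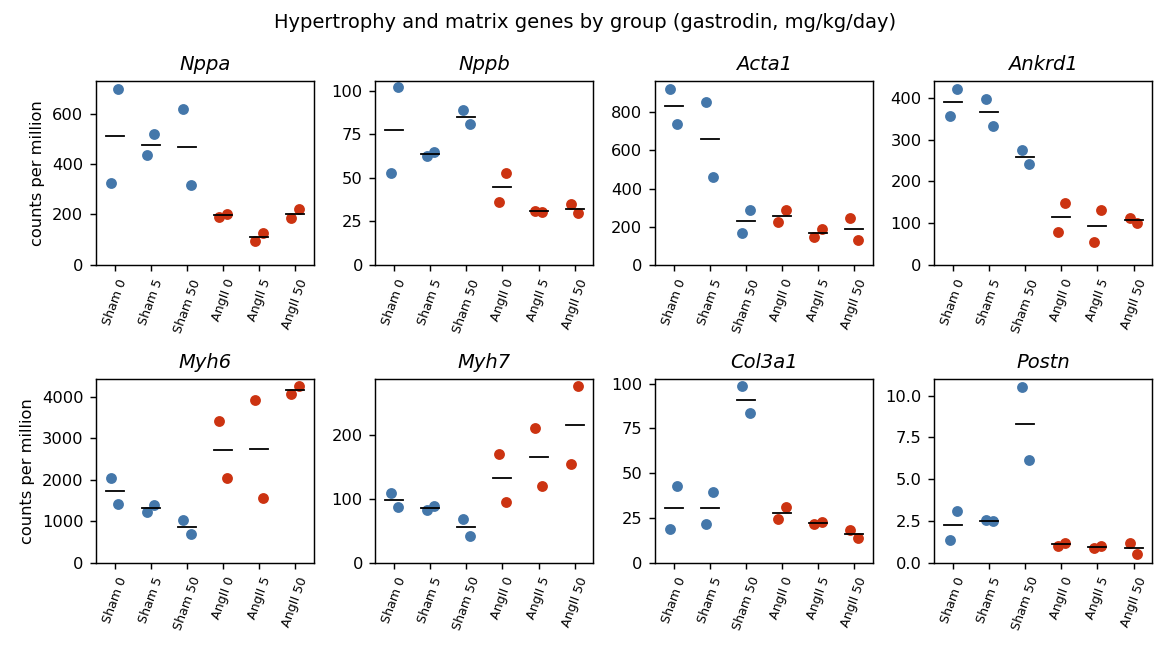
CPM (TMM-scaled) of 8 hypertrophy and matrix genes in the 6 groups, with 1 point per library and a line at the mean of 2 libraries. Nppa averaged 170 CPM in the AngII arm and 485 CPM in the sham arm, and Myh6 3202 and 1294 CPM.

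Among called genes whose libraries did not overlap between the arms, the largest rises were those of Mir208b (4.38 ± 2.42 against 0.105 ± 0.0366 CPM; log2 fold change 5.35 ± 0.43), the potassium channel subunit gene Kcnv2 (3.89 ± 0.46), Rnf207 (3.59 ± 0.31), the zinc finger gene Zfp612 (3.22 ± 0.34) and the endothelial receptor gene Notch4 (3.17 ± 0.42). Ice1 (2.95 ± 0.32), Gse1 (2.82 ± 0.55) and the scavenger receptor gene Scarf1 (2.81 ± 0.37) followed. The largest falls were those of the pseudogene Rps26-ps1 (-4.36 ± 0.42), the integrin-like gene Itgbl1 (-1.97 ± 0.32), the splicing regulator Mbnl1 (-1.97 ± 0.44) and Postn, followed by Col8a1 (-1.81 ± 0.30), Ankrd1, Bicc1 (-1.62 ± 0.24) and Cnn3 (-1.61 ± 0.28).

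Of 40 measured matrix and fibrosis genes 17 fell, 1 rose and 22 did not pass (18 fell and 2 rose when adjusted over the list alone), with the proteoglycan Bgn at -1.27 ± 0.19 and Fstl1 at -1.21 ± 0.18 among those that fell. Of 11 fibroblast markers 7 fell, over all genes and when adjusted over the list alone, among them Lum (-1.41 ± 0.25), Tcf21 (-1.13 ± 0.28) and Dcn (-0.95 ± 0.24). Of 18 fetal and hypertrophy genes 8 fell and 1 rose (8 and 2 when adjusted over the list alone). Of 42 ribosomal protein genes 33 fell, 35 when adjusted over the list alone, such as Rpl3 (-1.51 ± 0.25), Rps13 (-1.06 ± 0.20) and Rplp0 (-0.93 ± 0.20). Of 14 macrophage markers 3 fell, 4 when adjusted over the list alone, among them Mrc1 (-1.12 ± 0.32) and Lyz2 (-1.04 ± 0.32). Of 30 cell cycle genes 4 fell, 0 when adjusted over the list alone, including Mcm6 (-0.79 ± 0.25), Pcna (-1.09 ± 0.31) and Ccnb1 (-2.23 ± 0.73). Of 25 antioxidant genes 3 fell on both scales: Txn1 (-0.85 ± 0.19), Srxn1 (-0.88 ± 0.20) and Gpx1 (-0.90 ± 0.25).

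Of 21 calcium handling and ion channel genes 8 rose and 1 fell on both scales. Among them the L-type calcium channel Cacna1c (2.63 ± 0.27) and Kcnip2 (1.33 ± 0.23) rose, and the calcium release protein gene Trdn (-1.07 ± 0.18) fell. Of 12 endothelial markers 7 rose, 9 when adjusted over the list alone, among them Esam (1.36 ± 0.26) and Tie1 (1.26 ± 0.26). The lung markers lay mostly higher as well, at 2.13, 1.89, 0.56, 1.48, 0.78 and 0.75 (log2 deviation) in the AngII libraries against 0.13, -2.17, -0.38, 0.60, -0.90 and -2.28 in the sham libraries. Of 12 smooth muscle and pericyte markers 6 rose, 7 when adjusted over the list alone, among them Acta2 (1.40 ± 0.29), Notch3 (1.32 ± 0.28) and Abcc9 (0.90 ± 0.20). Of 9 red cell genes 5 rose, 6 when adjusted over the list alone, among them Hba-a2 (1.47 ± 0.25), Hbb-bs (1.39 ± 0.33) and Alas2 (1.28 ± 0.27). Camera called these 4 lists up (adjusted p = 0.00307 to 0.0479) and the 7 lists that fell down (adjusted p = 7.36e-19 to 0.0120). Adjusted p = 0.612 with an estimated correlation for each of the 11 lists, and 8 of 11 calls held in all 12 fits with 1 library left out each. The calcium handling call held in 7 (camera adjusted p up to 0.122). The fetal and hypertrophy call ended without AngII 5 mg number 4 (0.183) and the smooth muscle call without AngII 50 mg number 6 (0.0587).

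In all, 2241 genes rose and 1260 fell in edgeR's quasi-likelihood test, and the median gene lay at 0.10 (log2). That median depended on the processing. It was 0.29 with no filter, -0.020 with at least 1 CPM in 6 libraries (1964 higher, 1375 lower) and -0.040 with the GC trend removed. DESeq2 called 4617 genes and limma-voom 4491. The count was 1759 without AngII vehicle number 1, 2220 without AngII 5 mg number 3, 2005 without AngII 50 mg number 6, 2160 without sham vehicle number 8, 2264 without sham 50 mg number 12, and 4384 without AngII 5 mg number 4 and sham 50 mg number 12 together. It was 336 (282 higher, 54 lower) with the nuclear share of counts as a covariate, 1696 higher and 1755 lower with each library's trend on GC content removed, and 1227 higher and 26 lower on the authors' TPM, where the median gene lay at 0.22. With 1 library left out each, the fall of Ccnb1 kept its call in 1 of 12 fits (log2 fold change -3.99 to -1.85) and that of Col1a1 in 6 (-1.08 to -0.54). The falls of Mcm6, Lyz2, Mrc1, Pcna, Gpx1 and Dcn kept theirs in 4, 5, 6, 7, 7 and 11. The other calls of named genes held in all 12. On TPM the calls of Nppa (-0.89), Nppb (-0.45), Acta1 (-0.70), Igf2r (0.67) and Col1a1 (-0.22) ended, and with the covariate those of Myh6 (0.95), Myh7 (0.72), Acta1 (-1.06) and Igf2r (0.60). TPM carry no TMM scaling, so the larger nuclear share of the AngII arm (13.3 against 8.14%) can enter them. For the calls that ended on TPM, scaling and a weaker effect thus cannot be told apart.

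Gastrodin at 5 mg/kg/day against vehicle in AngII hearts asks what the low dose changed. Mlxip was higher than in AngII vehicle hearts (9.38 ± 3.95 against 0.918 ± 0.0977 CPM, SD, n = 2 each; log2 fold change 3.36 ± 0.38 SE, edgeR adjusted p = 0.0140), on chromosome 5 at 123394798 to 123457932 of GRCm38. Its level in sham vehicle was 4.69 ± 0.964 CPM. It was the 1 gene called, and the call was lost without AngII vehicle number 1 or 2. The next smallest p-values belonged to Cep85 (-1.75 ± 0.32), the zinc transporter Slc39a7 (-1.87 ± 0.37), Epn2 (1.92 ± 0.40) and the peroxidasin gene Pxdn (-1.67 ± 0.35), with edgeR adjusted p from 0.904 to 1. Of the hypertrophy and matrix genes, none passed: log2 fold changes were -0.83 ± 0.41 for Nppa, -0.53 ± 0.33 for Nppb, -0.62 ± 0.42 for Acta1, 0.32 ± 0.41 for Myh7, 0.01 ± 0.47 for Myh6, -0.11 ± 0.45 for Col1a1, -0.32 ± 0.40 for Col3a1, -0.22 ± 0.48 for Postn, 0.64 ± 0.68 for Igf2 and -0.26 ± 0.40 for Igf2r.

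Camera called 5 lists up (adjusted p = 1.97e-09 to 0.0234) and 2 down (0.0159 and 0.0229), while 0 of their members passed, over all genes or adjusted over the list alone. Adjusted p = 0.343 to 0.614 with an estimated correlation. The higher lists were 42 ribosomal protein genes (Rpl11 0.66 ± 0.30, Rps27 0.57 ± 0.30), 14 macrophage markers (C1qa 1.09 ± 0.47, Cd68 1.01 ± 0.53), 17 heat shock genes (Hspa8 0.63 ± 0.30, Hsp90aa1 0.87 ± 0.33), 21 genes of the unfolded protein response (Creld2 1.08 ± 0.38, Pdia4 0.90 ± 0.40) and 22 cytokine and chemokine genes (Cxcl14 0.81 ± 0.43). The lower lists were 8 mesothelial markers (Msln -2.20 ± 1.38) and 12 smooth muscle and pericyte markers (Tagln -1.66 ± 0.68, Acta2 -1.20 ± 0.50). The lung markers lay lower as well, at 0.56 and 1.48 (log2 deviation) against 2.13 and 1.89 in AngII vehicle, and liver genes summed to 29.8 and 113 CPM against 1.17 and 53.2 CPM. No list call held in all 12 fits with 1 library left out each (0 of 7), and 6 ended without AngII 5 mg number 4. There the ribosomal protein list turned down (camera adjusted p = 0.0661) and the smooth muscle list up (0.946). An unadjusted p under 0.05 was reached by 291 genes against 836 by chance; DESeq2 called 12 genes and limma-voom 1, and edgeR called 2 without AngII 5 mg number 3 and 11 without number 4.

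Gastrodin at 50 mg/kg/day against vehicle in AngII hearts asks what the high dose changed. Klhdc10, a substrate receptor of a ubiquitin ligase, fell (0.943 ± 0.0424 against 5.49 ± 0.0444 CPM, SD, n = 2 each; log2 fold change -2.54 ± 0.31 SE, edgeR adjusted p = 0.0245) and stood at 6.38 ± 1.54 CPM with 5 mg; it lies on chromosome 6 at 30401868 to 30455179 of GRCm38. The predicted gene Gm49394 was at least 142-fold higher (2.34 ± 0.0515 against 0 ± 0 CPM, edgeR adjusted p = 0.0245), since neither AngII vehicle library held a count. Of 12 fits with 1 library left out each, 6 and 7 kept these calls. Among the fits without a library of the compared groups, only that without AngII 50 mg number 5 kept either. Glycolysis genes rose as a list and mesothelial and epicardial markers fell as a list, and the lung markers lay lower as well, at 0.78 and 0.75 (log2 deviation) against 2.13 and 1.89 in AngII vehicle. Liver genes summed to 99.2 and 35.7 CPM against 1.17 and 53.2 CPM in AngII vehicle. Of 19 glycolysis genes 0 passed and 1 rose when adjusted over the list alone: Gpi1, glucose-6-phosphate isomerase, went from 59.6 ± 9.15 to 138 ± 11.9 CPM (1.21 ± 0.31), with hexokinase Hk1 at 0.63 ± 0.33 (camera adjusted p = 5.82e-05; adjusted p = 0.0477 with an estimated correlation).

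Of 8 mesothelial and epicardial markers 0 passed on either scale, with Msln at -2.42 ± 1.40 and Wt1 at -0.90 ± 0.69 (camera adjusted p = 2.73e-06; adjusted p = 0.0477 with an estimated correlation). Camera also called down 24 immediate-early genes (Atf3 -1.69 ± 0.46, Fosl2 -0.84 ± 0.30, Nr4a1 -1.46 ± 0.66), 40 matrix genes (Mmp14 -0.88 ± 0.50, Col18a1 -0.71 ± 0.39), 30 cell cycle genes (Tpx2 -1.16 ± 0.74, Ube2c -1.20 ± 0.80), 12 smooth muscle markers (Notch3 -0.63 ± 0.47, Pdgfrb -0.50 ± 0.40), 12 endothelial markers (Cldn5 -1.27 ± 0.58, Pecam1 -0.47 ± 0.35) and 19 genes of the insulin-like growth factor axis. In the last, Igf1 was at -1.49 ± 0.53, and 1 member, Igf2, fell when adjusted over the list alone (its sum with Gm49394 gave -0.56 ± 0.38). Without AngII 50 mg number 5 or 6 these were -3.07 or -0.70 for Igf1 and -6.85 or -2.85 for Igf2, and both passed over all genes without number 5. Camera called up 9 red cell genes (Hba-a2 0.95 ± 0.43) and 18 adult sarcomere genes (Myom1 1.06 ± 0.37, Tnnt2 0.38 ± 0.33). In these 8 lists 0 members passed over all genes and, Igf2 aside, 0 when adjusted over the list alone. Camera adjusted p ran from 5.67e-12 to 0.0380 (adjusted p = 0.115 to 0.682 with an estimated correlation). Of the 10 list calls, 4 (glycolysis, mesothelial, immediate-early and matrix) held in all 12 fits with 1 library left out each. The sarcomere call held in 3 (camera adjusted p up to 0.841). Without AngII 50 mg number 6 the red cell and growth factor calls ended (camera adjusted p = 0.638 and 0.0794) and the cell cycle list turned up (0.781). Without number 5 the smooth muscle call ended (0.946) and the endothelial list turned up (0.862).

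No hypertrophy or matrix gene passed: log2 fold changes were 0.05 ± 0.41 for Nppa, -0.46 ± 0.33 for Nppb, -0.45 ± 0.42 for Acta1, 0.70 ± 0.41 for Myh7, 0.61 ± 0.47 for Myh6, -0.38 ± 0.45 for Col1a1, -0.80 ± 0.40 for Col3a1, -0.37 ± 0.48 for Postn and -0.36 ± 0.40 for Igf2r. Among the 5 smallest p-values, Micall1 (2.36 ± 0.46), the transcription factor gene Creb1 (-2.92 ± 0.63) and Igf2 (-3.89 ± 0.80) had edgeR adjusted p = 1. An unadjusted p under 0.05 was reached by 315 genes against 836 by chance; DESeq2 called 15 and limma-voom 0. edgeR called 0 genes without AngII vehicle number 1, AngII 50 mg number 6 or either sham vehicle library, 1 without AngII vehicle number 2 and 13 without AngII 50 mg number 5.

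The series names the growth factor gene Igf2 and its receptor Igf2r in its title. Igf2 stood at 3.87 ± 0.902 CPM in AngII vehicle, 6.04 ± 2.99 in AngII 5 mg, 0.281 ± 0.352 in AngII 50 mg, 0.405 ± 0.0815 in sham vehicle, 3.82 ± 0.833 in sham 5 mg and 10.3 ± 2.38 in sham 50 mg (SD, n = 2 each). It lies on chromosome 7 at 142650766 to 142666816 of GRCm38, and Gm49394 spans it on the same strand from 142650769 to 142669942. Gm49394 held 2.34 ± 0.0515 CPM in AngII 50 mg, 4.11 ± 0.819 CPM in sham vehicle and 0 in the other groups, the reverse of Igf2. The sums of both were 3.87, 6.04 and 2.62 CPM in AngII and 4.51, 3.82 and 10.3 CPM in sham at 0, 5 and 50 mg. The log2 fold change of the sum was -0.23 ± 0.38 (SE) for AngII against sham vehicle and -0.56 ± 0.38 for 50 mg against vehicle in AngII, where Igf2 alone gave 3.24 and -3.89. For 50 mg against vehicle in sham it was 1.19 ± 0.38 (edgeR adjusted p = 0.333), where Igf2 alone gave 4.66 (edgeR adjusted p = 0.0491).

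**Figure D3:**
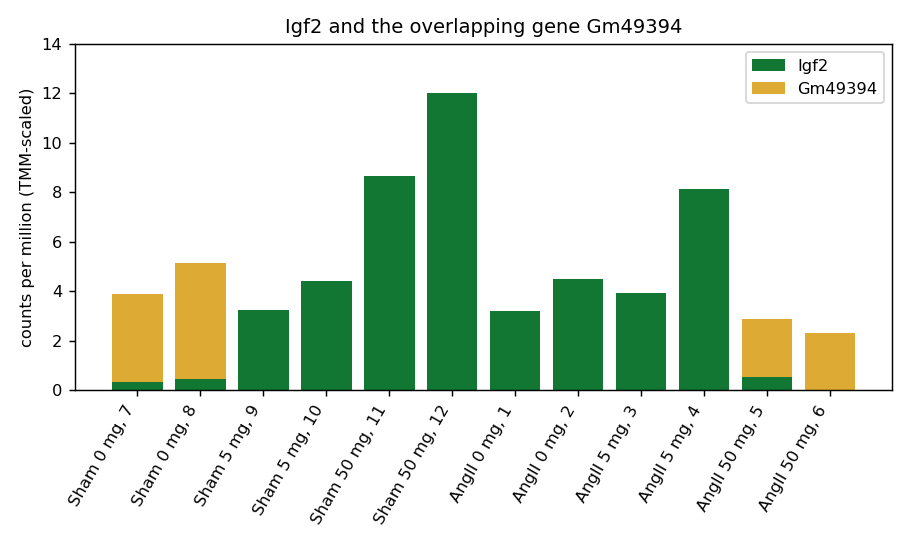
CPM (TMM-scaled) of Igf2 and of Gm49394, which overlaps it on the same strand, stacked in each of the 12 libraries. Gm49394 takes most of the counts in sham vehicle and AngII 50 mg, where Igf2 averages 0.405 and 0.281 CPM.

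Gastrodin at 5 mg/kg/day against vehicle in sham hearts asks what the low dose changed without angiotensin II. Baiap2l1, an adaptor protein of actin assembly, fell from 20.96 ± 9.72 to 0.808 ± 0.424 CPM (SD, n = 2 each; log2 fold change -4.71 ± 0.64 SE, edgeR adjusted p = 0.0360), on chromosome 5 at 144264526 to 144358112 of GRCm38, where it overlaps Bri3 on the opposite strand. Gm49394 was at least 137-fold lower and the pseudogene Gm2274 at least 27.1-fold lower, with no count in either 5 mg library. Cdo1, cysteine dioxygenase, was at least 41.1-fold higher without passing (edgeR adjusted p = 0.0732), and Gm42688 was at -2.20 ± 0.38 (0.228). The lists for fatty acid oxidation and red cells lay lower by camera, though not with an estimated correlation (adjusted p = 0.299 and 0.299).

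Over all genes 0 members of any list passed. Of 9 red cell genes 6 fell when adjusted over the list alone, among them Hba-a2 (-1.53 ± 0.44) and Hba-a1 (-1.41 ± 0.49). The other lower lists were 30 fatty acid oxidation genes (Pdk4 -1.33 ± 0.44, Hadh -0.85 ± 0.27), 41 oxidative phosphorylation genes (Ndufv2 -0.50 ± 0.31, Sdhb -0.46 ± 0.32), 21 calcium handling genes (Hcn2 -1.18 ± 0.42, Atp2a2 -0.45 ± 0.29) and 18 sarcomere genes (Des -0.43 ± 0.36), with 0 members adjusted over the list alone. The higher lists were 25 interferon genes (Oas1a 1.87 ± 0.51, Gbp3 0.93 ± 0.38), 14 macrophage markers (Cd68 0.75 ± 0.53, C1qb 0.53 ± 0.47), 12 smooth muscle markers (Tagln 1.70 ± 0.68, Acta2 1.01 ± 0.50), 40 matrix genes (Ltbp2 2.53 ± 0.63, Col14a1 1.13 ± 0.52), 24 immediate-early genes (Atf3 1.01 ± 0.46, Btg2 0.54 ± 0.33), 14 glucocorticoid-responsive genes (Errfi1 1.41 ± 0.32, Tsc22d3 0.79 ± 0.34) and 8 fat cell markers (Car3 at least 49.9-fold). Adjusted over the list alone, Egr2 (at least 35.2-fold), Errfi1 and Car3 rose in the immediate-early, glucocorticoid and fat cell lists, and 0 members of the others. Camera adjusted p ran from 2.43e-09 to 0.0359 (adjusted p = 0.299 to 0.493 with an estimated correlation). The summed level of 25 liver genes was 79.7 CPM in sham 5 mg number 10, 0.354 CPM in number 9, and 1.72 and 0.775 CPM in sham vehicle. The fat cell markers too lay higher in number 10 alone. Their median log2 deviation was 0.54 there, -0.84 in number 9, and -0.84 and -0.53 in sham vehicle. Whether the rises of Car3 and Cdo1 came with the liver genes was not tested.

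An unadjusted p under 0.05 was reached by 689 genes against 836 by chance; DESeq2 called 32 and limma-voom 0. edgeR called 0 genes without sham vehicle number 7 or 8 or sham 5 mg number 9, and 3 other genes without sham 5 mg number 10. The calls of Baiap2l1 and Gm49394 held in 8 and that of Gm2274 in 4 of 12 fits with 1 library left out each. None held in a fit without a library of the compared groups. The list calls rest largely on single libraries: 9 of 12 ended without sham 5 mg number 10, with camera adjusted p of 0.0764 (macrophage) to 0.933 (oxidative phosphorylation). Without sham vehicle number 7, 7 ended, and the matrix list turned down (camera adjusted p = 0.722). The 3 that held in all 12 fits with 1 library left out each were fatty acid oxidation, red cell and immediate-early genes.

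Gastrodin at 50 mg/kg/day against vehicle in sham hearts asks what the high dose changed without angiotensin II. Errfi1 rose from 1.96 ± 0.265 to 12.2 ± 2.69 CPM (SD, n = 2 each; log2 fold change 2.63 ± 0.33 SE, edgeR adjusted p = 0.00654) and the cell cycle inhibitor Cdkn1a, known like it to respond to glucocorticoids, from 3.37 ± 0.0446 to 13.5 ± 1.55 CPM (2.00 ± 0.32, edgeR adjusted p = 0.0289). Ucp3, the muscle mitochondrial uncoupling protein, fell (0.459 ± 0.392 against 6.29 ± 1.45 CPM; -3.80 ± 0.61), as did the potassium channel Kcnj14 (-4.13 ± 0.61) and Baiap2l1 (-4.08 ± 0.62). Matrix, macrophage and interferon genes lay higher as lists, and genes of fatty acid oxidation, respiration and the sarcomere lower, by camera but not with an estimated correlation (adjusted p = 0.104 to 0.118).

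edgeR called 14 genes higher and 11 lower. Rpl21 (16.8 ± 0.292 against 0.786 ± 0.0337 CPM; 4.42 ± 0.34, edgeR adjusted p = 0.000131) and Rps26-ps1 (6.06 ± 0.74) rose and Rpl3-ps2 (-3.74 ± 0.61) fell, all of a family with near-identical copies that makes their counts uncertain. Gdpd3, a lysophospholipase D gene on chromosome 7 at 126766334 to 126775649 of GRCm38, was at least 706-fold higher, with no count in sham vehicle.

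Of 14 glucocorticoid-responsive genes 2 rose, Errfi1 and Cdkn1a, and 9 when adjusted over the list alone, among them Tsc22d3 (1.68 ± 0.35) and Fkbp5 (2.08 ± 0.53). Of 40 matrix genes 0 passed and 21 rose when adjusted over the list alone, among them Loxl1 (15.3 ± 0.594 against 5.35 ± 1.16 CPM; 1.51 ± 0.29), Col15a1 (1.84 ± 0.42) and Fbn1 (1.32 ± 0.33). Adjusted over the list alone, 4 of 11 fibroblast markers rose (Dcn 1.39 ± 0.41, Col1a2 1.39 ± 0.39), as did 4 of 14 macrophage markers (C1qa 1.52 ± 0.47, Csf1r 1.25 ± 0.42) and 6 of 25 interferon genes (Oas1a 1.95 ± 0.51, Gbp2 1.92 ± 0.49). Of 17 heat shock genes 5 rose and 1 fell on that scale (Hspa1a 3.16 ± 0.60, Dnaja1 1.22 ± 0.30), and of 24 immediate-early genes 2 rose (Egr2 at least 44.3-fold and Socs3 by 1.83 ± 0.47, with Zfp36 at 1.28 ± 0.54). No member of the cytokine list (22 genes; Vcam1 1.67 ± 0.47, Ccl9 2.44 ± 0.87), the unfolded protein list (21; Hyou1 1.27 ± 0.47, Dnajb11 0.84 ± 0.37) or the smooth muscle list (12; Rgs5 0.65 ± 0.30, Notch3 0.72 ± 0.48) passed on either scale. Of 19 genes of the insulin-like growth factor axis 1 rose, Igf2, and adjusted over the list alone 1 rose and 1 fell (Igfals -4.12 ± 1.07), with the binding protein Igfbp7 at 1.07 ± 0.35.

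Of 30 fatty acid oxidation genes 1 fell, Ucp3, and 14 when adjusted over the list alone, among them Pdk4 (-2.48 ± 0.45), Mlycd (-1.35 ± 0.26) and Hadh (-1.20 ± 0.28). Adjusted over the list alone, 6 of 9 red cell genes fell (Hba-a2 -2.40 ± 0.45, Hba-a1 -1.58 ± 0.49), as did 4 of 12 cardiomyocyte markers (such as Ckm, -1.09 ± 0.38), 2 of 18 sarcomere genes (Myom2 -1.12 ± 0.28, Ldb3 -1.12 ± 0.30) and 2 of 18 fetal and hypertrophy genes (Acta1 -1.87 ± 0.44, Csrp3 -1.19 ± 0.34). No member of the lists for oxidative phosphorylation (41 genes; Cox4i1 -1.23 ± 0.39, Atp5a1 -0.85 ± 0.31), glycolysis (19; Pfkm -0.85 ± 0.29, Ldhb -0.86 ± 0.31) or calcium handling (21; Cacna1c -1.26 ± 0.45, Pln -0.77 ± 0.28) passed on either scale. Camera called 11 lists up (adjusted p = 1.72e-20 to 0.0390) and 8 down (adjusted p = 2.72e-19 to 0.0120), with adjusted p = 0.104 to 0.406 with an estimated correlation. Fry, which asks only whether a list moved 1 way, called 14 lists in this comparison. Liver genes summed to 49.8 and 56.2 CPM in the 50 mg libraries, against 1.72 and 0.775 CPM in sham vehicle, and number 12 held the 10.8% of ribosomal RNA.

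**Figure D4:**
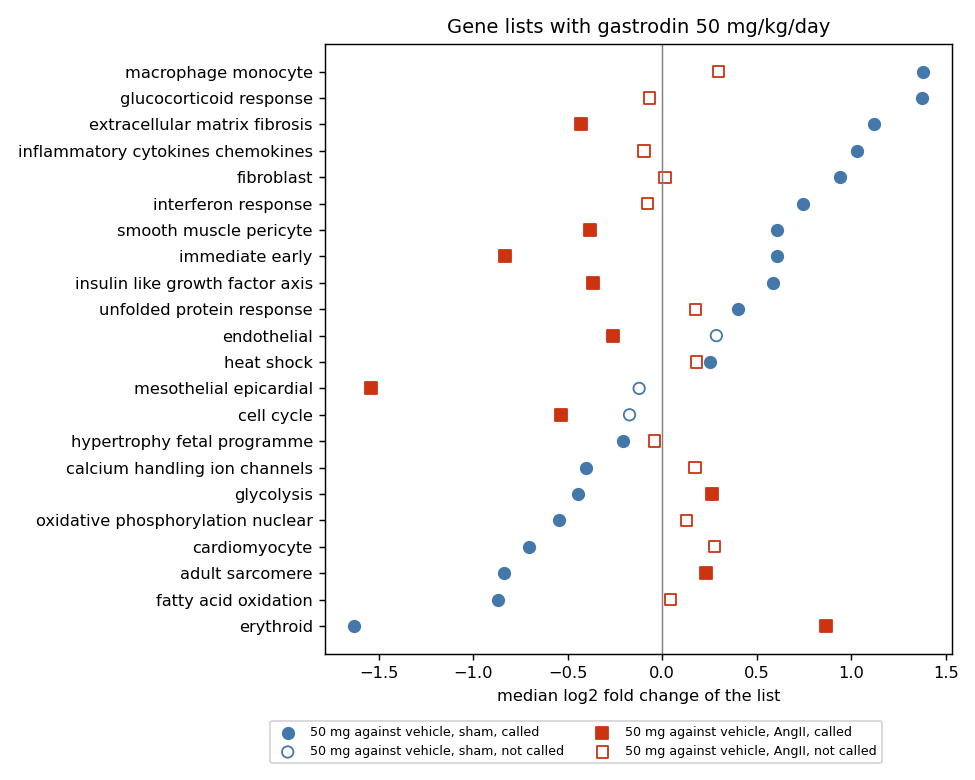
Median log2 fold change of each gene list called with 50 mg gastrodin in sham (circles) or AngII hearts (squares), with filled marks where camera's adjusted p was under 0.05 at its preset correlation. Matrix genes lay at 1.12 in sham and -0.43 in AngII, and with an estimated correlation only glycolysis and mesothelial markers in AngII stayed called.

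Without adjustment, 1542 genes had p under 0.05, against 836 by chance; DESeq2 called 281 and limma-voom 20. The count of 25 was 1 without sham vehicle number 7, 9 without sham 50 mg number 12, 42 and 39 without AngII vehicle number 1 or 2, 60 and 65 without AngII 5 mg number 3 or 4, and 62 with the nuclear share as a covariate. The calls of the genes named as called held in 8 (Cdkn1a, Igf2 and Rpl3-ps2) to 12 of 12 fits with 1 library left out each. Of the list calls, 14 of 19 held in all 12. The growth factor, heat shock, smooth muscle, fetal and hypertrophy and calcium handling calls did not (camera adjusted p up to 0.170).

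Averaged over both doses, gastrodin against vehicle in AngII hearts changed 0 genes in edgeR's quasi-likelihood test, where 254 reached an unadjusted p under 0.05; DESeq2 called 10 and limma-voom 0. The smallest p-values belonged to Epn2 (7.24 ± 0.691 against 2.03 ± 1.30 CPM, SD, n = 4 and 2; log2 fold change 1.84 ± 0.37 SE), Mlxip (1.66 ± 0.33), Klhdc10 (-1.16 ± 0.24), Slc39a7 (-1.39 ± 0.30) and the protocadherin gene Pcdhgc3 (2.29 ± 0.51), each with edgeR adjusted p = 1.00; Slc39a7 and Pcdhgc3 share exons with other genes and are uncertain. edgeR called 1 gene without AngII vehicle number 2 and 6 without AngII 50 mg number 5. Camera called 6 lists up (ribosomal protein, heat shock, macrophage, red cell, glycolysis and unfolded protein response) and 4 down (immediate-early, mesothelial, matrix and smooth muscle). Of their members 0 passed, and adjusted over the list alone 1 glycolysis gene rose (Gpi1; adjusted p = 0.0810 to 0.776 with an estimated correlation). Only the mesothelial call (1 of 10) held in all 12 fits with 1 library left out each. Further, 8 calls ended without AngII 5 mg number 4, where the ribosomal protein list turned down (camera adjusted p = 0.236).

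Comparing 50 with 5 mg/kg/day in AngII hearts asks whether the dose mattered. Mlxip (0.893 ± 0.130 against 9.38 ± 3.95 CPM, SD, n = 2 each; log2 fold change -3.39 ± 0.38 SE, edgeR adjusted p = 0.00635) and Klhdc10 (-2.76 ± 0.31, edgeR adjusted p = 0.00635) were lower at 50 mg, and Gm49394 was at least 159-fold higher. Cep85 (1.92 ± 0.32) and Igf2 (-4.53 ± 0.82) did not pass (edgeR adjusted p = 0.200 and 0.316). Camera called 9 lists down, led by immediate-early and ribosomal protein genes and the insulin-like growth factor axis, and 3 up (sarcomere, glycolysis and calcium handling). Of their members 0 passed over all genes, and adjusted over the list alone 2 genes of the growth factor axis, Igf1 (-1.84 ± 0.54) and Igf2, and 1 glucocorticoid-responsive gene, Errfi1 (-1.14 ± 0.31), fell (adjusted p = 0.102 to 0.517 with an estimated correlation). The sum of Igf2 and Gm49394 gave -1.20 ± 0.38 (edgeR adjusted p = 1). Without adjustment, 396 genes had p under 0.05; DESeq2 called 20 and limma-voom 2. edgeR called 0 genes without AngII 50 mg number 6, 13 without number 5, and 9 and 18 without AngII 5 mg number 3 or 4. Of the list calls only that of the growth factor axis (1 of 12) held in all 12 fits with 1 library left out each, and calcium handling held in 4 (camera adjusted p up to 0.562) and glucocorticoid-responsive genes in 2 (up to 0.578). Without AngII 50 mg number 5 or 6 Igf1 was at -3.42 or -1.04 and Igf2 at -7.49 or -3.47. Both passed over all genes without number 5. Without AngII 5 mg number 4 the ribosomal protein and macrophage lists turned up (camera adjusted p = 0.0277 and 0.689), as did the cell cycle list without AngII 50 mg number 6 (0.972).

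The interaction asks whether gastrodin acted differently in AngII and sham hearts. At 5 mg, Baiap2l1 differed (log2 gastrodin effect 6.69 ± 0.85 SE higher in AngII than in sham, edgeR adjusted p = 0.0473, 2 libraries in each of 4 groups). Mlxip (3.28 ± 0.51, 0.180) and Pcdhgc3 (4.11 ± 0.77, 0.465) did not pass. At 50 mg, 5 genes differed. The gastrodin effect was lower in AngII than in sham for Errfi1 (-3.96 ± 0.45, edgeR adjusted p = 0.00466) and Rpl21 (-4.40 ± 0.45, 0.00187). It was also lower for Igf2 (-8.55 ± 1.14, 0.0186) and the predicted gene Gm10036 (-5.85 ± 0.83, 0.0293), picked after its value was seen. For Gm49394 the effect was higher in AngII. These values compare effects and not levels. The sum of Igf2 and Gm49394 gave -1.75 ± 0.54 (edgeR adjusted p = 0.528). Cdkn1a was at -2.50 ± 0.44 (0.129).

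By camera, whole lists also moved apart at 50 mg, though none passed with an estimated correlation. Here higher and lower refer to the gastrodin effect in AngII less that in sham, and not to levels. Summed liver genes differed here too. They stood at 49.8 and 56.2 CPM against 1.72 and 0.775 CPM in sham vehicle, and at 99.2 and 35.7 CPM against 1.17 and 53.2 CPM in AngII vehicle. Sham 50 mg number 12 also held 10.8% of its counts in ribosomal RNA loci. Of 40 matrix genes 0 passed over all genes and 19 were lower when adjusted over the list alone, with Col3a1 at -2.36 ± 0.57 and Col15a1 at -2.33 ± 0.58 (camera adjusted p = 6.72e-24; adjusted p = 0.0935 with an estimated correlation). Glycolysis genes were higher (1 of 19, Gpi1 at 1.67 ± 0.44, adjusted over the list alone; camera adjusted p = 3.02e-06; adjusted p = 0.0600 with an estimated correlation). Red cell genes were higher (6 of 9 adjusted over the list alone; Hba-a2 3.34 ± 0.62), as were sarcomere genes (0 of 18; Myom1 1.91 ± 0.52), and immediate-early (3 of 24; Atf3 -2.88 ± 0.65) and macrophage genes (0 of 14; Csf1r -1.81 ± 0.59, C1qb -1.17 ± 0.66) were lower. In all, camera called 18 lists at 50 mg, 8 up and 10 down (adjusted p = 0.0600 to 0.543 with an estimated correlation), and 10 at 5 mg, 5 each way (adjusted p = 0.167 to 0.590 with an estimated correlation). An unadjusted p under 0.05 was reached by 514 genes at 5 mg and 1159 at 50 mg; DESeq2 called 14 and 114, and limma-voom 0 and 6. The single 5 mg call was lost without sham number 7, 9, 10, 11 or 12, and edgeR called 2 genes without AngII vehicle number 2 and 10 without AngII 5 mg number 4, where the immediate-early and ribosomal protein lists also turned (camera adjusted p = 0.740 and 0.414). At 50 mg it called 2 without sham vehicle number 7, 8 without AngII vehicle number 2 or sham 50 mg number 11, 16 without AngII 5 mg number 3 or AngII 50 mg number 5, and 23 without AngII 5 mg number 4. In all 12 fits with 1 library left out each, 2 of 10 list calls held at 5 mg (red cell and mesothelial genes) and 13 of 18 at 50 mg. At 50 mg the fetal and hypertrophy call held in 3 and the endothelial call in 7. The 50 mg calls of Gm10036, Igf2 and Errfi1 held in 7, 10 and 11.

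Whether gastrodin moved genes against the AngII change was asked by the covariance, across 16723 genes, of the AngII effect in vehicle hearts with the gastrodin effect in AngII hearts. It was -0.645 at 5 mg (Pearson r = -0.322) and -0.566 at 50 mg (r = -0.273). Both effects share the AngII vehicle libraries with opposite sign, and 20 simulations with no effect gave -0.714 ± 0.0282 and -0.716 ± 0.0291 (SD), with r = -0.487 and -0.488. The observed values were less negative than these by 0.0690 and 0.149. With no AngII vehicle library shared, the covariances were 0.152 and 0.261, and with a prior count of 5 as well they were -0.00405 and 0.0786. Leaving out any of the 8 libraries in turn gave -2.22 to -0.765 at 5 mg and -2.05 to -0.818 at 50 mg, where simulations with no effect gave -2.05 to -0.876 and -2.05 to -0.868. Observed less simulated, these values ran from -0.787 (without AngII 5 mg number 3) to 0.183 (without number 4) and from -0.260 (without AngII 50 mg number 6) to 0.238 (without AngII vehicle number 1). The side of the no-effect value on which they lay differed between these fits. The filter on low counts was run again in each fit, by group, so the genes could change as well. At 50 mg the covariance was -0.818 without AngII 5 mg number 3 (simulated -0.868), a library outside that comparison. The loss of a library and a change of genes thus cannot be told apart here. Genes are not independent replicates, so no p-value is given.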

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

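The tests of summed Igf2 and Gm49394 counts, of liver genes, of other splits of the libraries, of unspliced RNA, of the nuclear share and of exchanged labels were chosen only after the result was seen.

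Sham 50 mg number 12 stood apart from the other sham libraries, with 10.8% of counts in ribosomal RNA loci against 0.088 to 0.959%, and 63.9% in mitochondrial genes against 71.7 to 74.5%. Nppb was at 52.8 CPM in AngII vehicle number 2, against 29.8 to 36.3 CPM in the other AngII libraries. These were 3 of 32 tests of the kind, and chance gives about 1 in 20. The gastrodin effect differed between AngII and sham, by an interaction test, for Baiap2l1 at 5 mg (log2 6.69) and for Errfi1 (-3.96), Rpl21 (-4.40), Igf2 (-8.55), Gm10036 (-5.85) and Gm49394 (21.85) at 50 mg. The value of Gm49394 is a fitted one that depends on the prior count and is no bound. The sum of Igf2 and Gm49394 gave -1.75 ± 0.54 (SE, edgeR adjusted p = 0.528). Counts of Rpl21 are uncertain because of near-identical copies.

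Igf2 and Gm49394 share exons and replace each other between groups. A candidate explanation is that reads of 1 locus were counted to either gene: the summed counts gave a log2 fold change of -0.56 ± 0.38 (SE) for 50 mg against vehicle in AngII and -0.226 ± 0.38 for AngII against sham vehicle, both within 2 SE of 0. The sum gave 1.19 ± 0.38 for 50 mg in sham, which argues against it as the whole cause there, and gastrodin stays open as untested. For 50 against 5 mg in AngII (-1.20 ± 0.38) and the interaction at 50 mg (-1.75 ± 0.54) the sum was also over 2 SE from 0, in the direction of Igf2. These comparisons share libraries, and none of these sums passed after adjustment. In all, 95 genes were at 0 in both libraries of a group and at 50 counts or more in both of another; 12.6% of them overlapped a gene on the same strand, or were pseudogenes or ribosomal protein genes, against 13.3% of genes of like counts (ratio 0.952). As a set they thus held no excess of such genes. None of the 12 hepatocyte genes given below has such an overlap or copy, so liver genes lower this share. The ratio therefore cannot decide the question for the other genes. Copies in other families, such as the Mup genes, were not counted. Liver RNA in some of the libraries may account for part of them: 12 were in the hepatocyte list (12.6% against 0.421% of genes of like counts), whose summed level was 1.72 and 0.775 CPM in sham vehicle. That list has only 25 genes. Members of the same families outside it, such as Apoa5, Serpina1d and Serpina1e, were also at 0 in sham vehicle. The 12.6% can thus be too low a share for liver genes. Of 1000 random pairings of the libraries, 119 gave as many such genes (highest 157), so their number does not need the treatment groups.

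The 3501 genes called between the arms averaged over dose were reached by 1 of 100 splits of the libraries within doses, the real one. The highest other gave 2245, and exchanges AngII 5 mg number 4 with sham 5 mg number 10. This argues against chance but does not exclude it, since 100 splits can show no share under 1 in 100. With each library's GC trend removed 3451 were called, and 2835 of the 3501 stayed called in the same direction (1659 higher, 1176 lower), which argues against GC content as the whole cause. It may have a part, since 582 higher calls ended, 579 lower ones were new, and log2 fold change rose with GC across the called genes (Spearman rho 0.262, genes not being independent). Log2 fold change also rose with exon length (rho 0.172), with a median of 5310 bases for higher and 3443 for lower calls. A part of transcript length in the calls was not tested. With the nuclear share as a covariate 336 were called, and since the share itself differed between the arms (13.3 and 8.14%), the share and the treatment cannot be told apart. More unspliced RNA in the AngII libraries also stays open: rho with intron length was 0.0270, while 7 of 10 nuclear-retained RNAs were called higher (median 1.09). Over all genes 2241 of 16723 were called higher. Mir208b, the largest rise among the genes named for this comparison, is 1 of the 7 and is not independent support. An exchange of the labels of numbers 4 and 10 also stays open by the rule set for it. The scale ran from sham (0) to AngII (1), set by genes that part the arms in the vehicle and 50 mg libraries. On it number 4 lay at 0.339, on the sham side, and number 10 at 0.199, within 2 SD (0.158 each) of the middle. Sham vehicle number 7, placed when left out, lay at 0.313, so number 10 does not stand out from the sham libraries. The AngII vehicle and 50 mg libraries, placed likewise, lay at 0.650 to 1.15. Number 10 lay below all of these, which argues against the exchange but rests on 1 library. A wrong label of number 4 alone needs no partner and stays open too. Whether the labels of the 2 arms were exchanged cannot be told apart from the treatment either. The fetal and hypertrophy list had a median of -0.0239, with Nppa, Nppb, Acta1 and Ankrd1 lower in AngII and Myh7 higher. An effect of AngII is the biological explanation that the design names, and it holds only if the labels do.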

How the results depend on the processing

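Overlapping genes summed, the nuclear share as a covariate, libraries 4 and 12 left out together and the GC trend removed were chosen only after the result was seen. No paired analysis was possible because each number occurs once. Where a group loses a library, the lone library is assumed to vary like the other groups. The filter, run again by group, is then looser, so genes of lower count can enter every comparison of that fit. Values of named genes under alternatives kept their direction and side of the threshold in 893 of 1069 cases for AngII vehicle (67 lost and 101 gained a call, 8 changed sign), 1153 of 1267 for the average, 643 of 674 and 787 of 819 for 5 and 50 mg in AngII, 644 of 693 and 1137 of 1268 in sham, 116 of 125 for both doses, 152 of 174 for dose, and 104 of 123 and 314 of 346 for the interactions. DESeq2 size factors in edgeR, the 1.5-fold limit and the GC trend removed left each count of called genes within 1.5 times; the cause of the changes below was not tested, except that no filter tests more genes and left-out libraries are fewer. Depth of 4.49 to 15.2 M nuclear counts limits genes of low count.

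For AngII against sham vehicle (10 called), the DESeq2 Wald test called 718, limma-voom 5, no filter 1109, only the compared groups 233, mitochondrial and haemoglobin genes left out 6, overlapping genes summed 2, the covariate 86 and libraries 4 and 12 left out 448. For the average (3501), TPM gave 1253 and the covariate 336. In the order 5 mg and 50 mg in AngII, 5 mg and 50 mg in sham, both doses in AngII, dose, interaction at 5 mg and at 50 mg (1, 2, 3, 25, 0, 3, 1 and 5), the DESeq2 Wald test called 12, 15, 32, 281, 10, 20, 14 and 114, and no filter 60, 62, 152, 354, 52, 67, 93 and 231. limma-voom called 0 for 50 mg in AngII, 5 mg in sham and the interaction at 5 mg. At least 1 CPM in 6 libraries gave 1 for 50 mg in AngII, 0 for 5 mg and 14 for 50 mg in sham, and 0 and 2 for the interactions. Only the compared groups gave 0, 1, 0, 65, 1, 0 and 0 in that order up to the interaction at 5 mg. Mitochondrial and haemoglobin genes left out gave 0 for the interaction at 5 mg. TPM gave 0 and 0 in AngII, 1 for 5 mg in sham, 0 for dose and 2 for the interaction at 5 mg. Overlapping genes summed gave 1 for 50 mg in AngII and 3 for the interaction at 50 mg. The covariate gave 1 for 50 mg in AngII, 1 and 62 in sham and 13 for the interaction at 50 mg. Libraries 4 and 12 left out gave 8 for 5 mg in AngII, 1 for 5 mg in sham, 16 for dose, and 3 and 9 for the interactions. Of 119 list calls, 2 held with an estimated correlation and 24 with fry, which called 25 lists in all. The covariances of -0.645 and -0.566 became -0.198 and -0.119 with a prior count of 5 (simulated with no effect -0.239 and -0.239), -0.109 and -0.0211 with at least 1 CPM in 6 libraries (simulated -0.123 and -0.123), and 0.152 and 0.261 with no shared library, which removes the built-in negative term.

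Leaving out each library in turn gave 0 to 535 genes for AngII vehicle, 1759 to 5143 for the average, 0 to 11 and 0 to 13 for 5 and 50 mg in AngII, 0 to 4 and 1 to 65 in sham, 0 to 6 for both doses, 0 to 18 for dose, 0 to 10 and 2 to 23 for the interactions, and 101 to 123 list calls. The covariances ran from -2.22 to -0.765 and from -2.05 to -0.818, where simulations with no effect gave -2.05 to -0.876 and -2.05 to -0.868. Log2 fold changes that changed sign ran, for AngII vehicle, from -0.0455 to 0.83 (Myh7), -0.63 to 0.59 (Col3a1) and -0.98 to 0.65 (Col1a1). For 5 mg in AngII they ran from -0.16 to 0.80 (Myh7), -0.83 to 0.52 (Myh6), -0.50 to 0.41 (Col1a1) and -0.87 to 0.15 (Igf2r), and for 50 mg in AngII from -0.0642 to 0.17 (Nppa), -1.02 to 0.12 (Postn) and -0.78 to 0.17 (Col1a1). Lists that turned had camera adjusted p, for 5 mg in AngII, from 2.20e-26 to 0.0661 (ribosomal protein) and 0.00462 to 0.946 (smooth muscle), and for 50 mg in AngII from 1.76e-09 to 0.788 (cell cycle) and 1.60e-04 to 0.862 (endothelial). They had 6.53e-07 to 0.824 for matrix genes with 5 mg in sham and 8.32e-19 to 0.680 for ribosomal protein genes with both doses. For dose they had 2.62e-08 to 0.972 (cell cycle), 1.36e-22 to 0.0277 (ribosomal protein) and 0.00239 to 0.888 (macrophage), and for the interaction at 5 mg 1.29e-08 to 0.740 (immediate-early) and 3.90e-22 to 0.414 (ribosomal protein).

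Other changes of sign concerned Myh6 with 5 mg in AngII (0.01), at -0.00556 with DESeq2 size factors, -0.00556 with DESeq2, -0.14 with limma-voom, -0.00359 on TPM, -0.13 with the covariate and -0.0218 with the GC trend removed. On TPM, Col3a1 (0.37) and Col1a1 (0.0645) in AngII vehicle, Igf2 in the average (0.0204) and Col1a1 with 5 mg in AngII (0.0859) did so. With overlapping genes summed, Igf2 in AngII vehicle (-0.23), Gm42688 with 5 mg in sham (0.0595) and Gm49394 with 50 mg in AngII (-0.56), dose (-1.20) and the interaction at 50 mg (-1.75) did so, by the construction of the sum. Without libraries 4 and 12, Col1a1 (0.0685) and Igf2r (0.15) with 5 mg in AngII did so.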

Other observations

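The test of liver RNA against the treatment groups was chosen only after the result was seen.

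Camera called 10 lists in none of the 10 comparisons. Their smallest adjusted p over the comparisons belonged to atrial cardiomyocyte genes (9 tested; 0.1003), B cell genes (12 tested; 0.111), brown fat cell genes (6 tested; 0.222), circadian clock genes (18 tested; 0.230), mitochondrially encoded genes (13 tested; 0.0888), neutrophil genes (5 tested; 0.0822), renin-angiotensin genes (10 tested; 0.206), Schwann cell and nerve genes (8 tested; 0.0547), skeletal muscle genes (7 tested; 0.209) and T and NK cell genes (8 tested; 0.124).

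Genes of hepatocytes, the main cells of the liver, were counted in some of the heart libraries. All 25 genes of a hepatocyte list had counts, the most abundant being Alb, Apoa1, Cyp2e1, Ahsg and Apoa2, and Alb was highest at 42.4 CPM in AngII 50 mg number 5. Their summed level was 1.17 and 53.2 CPM in AngII vehicle, 29.8 and 113 CPM in AngII 5 mg, 99.2 and 35.7 CPM in AngII 50 mg, 1.72 and 0.775 CPM in sham vehicle, 0.354 and 79.7 CPM in sham 5 mg, and 49.8 and 56.2 CPM in sham 50 mg. As a hypothesis, liver RNA as 1 source may account for them: the median Spearman rho of the other 24 genes with Alb across the 12 libraries was 0.937. The treatment groups did not order them, since libraries of 1 group differed by up to 225-fold (sham 5 mg). How such RNA entered was not tested.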
